A study of Homo sapiens with 12 samples.

How the data were processed

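RNA was measured in T47D-YB cells, a human breast cancer line in which a pSG5-PR-B vector for progesterone receptor B had been stably integrated, per the labels. Cells were left unsynchronized or were synchronized with nocodazole, a drug that depolymerizes microtubules, before the G2/M phase. They then received R5020, a synthetic progestin, or its ethanol vehicle, and RNA was taken after 6 hours. This gave 4 groups of 3 arrays, 12 arrays in all, on the Illumina HT-12 v4 platform, per the labels and the series description. Total RNA was extracted with Trizol, cleaned and treated with DNase on RNeasy columns, and labelled as biotinylated cRNA with the Ambion MessageAmp kit, per the labels' protocols. The R5020 dose is not restated because its notation in the series description allowed more than 1 reading.

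Groups were taken from the sample titles, descriptions and source names, which matched each other. A separate label field for cell synchronization followed the treatment instead and contradicted those names, so it was not used. The labels number the arrays of each group as replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these arrays.

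The deposited intensity values were mean bead signals per probe, neither background-subtracted nor normalized between arrays, per the file headers and the values themselves. The deposited detection p-values set each probe against the negative control beads of its own array, per the file headers, and their equal steps corresponded to 770 negative controls. The scanner, its software, the annotation version and the genome build of the probe coordinates were not given in the sources used here. A further 48 per-array columns carried names that match no sample label and were left out. The authors' processed table was found, from its values, to hold linear intensities that had been quantile normalized and averaged over the probes of each symbol. Of its 31415 entries, 31414 matched a symbol of the probe file, with a median relative difference of 1.2e-05% from values rebuilt that way. Its column medians lay between 114.1 and 114.4, each column correlated with its own array at 0.999941 or more, and no column correlated with another array above 0.996102. It was not centred and held no ratio, so scale, centring and direction were settled, and it served as an alternative.

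Precision was limited by the number of arrays and by signal over background. Between 19797 and 21278 of the 47322 probes were detected per array (41.8% to 45%) at a detection p under 0.05, and the median signal per array ranged from 108.1 to 121.7 before normalization.

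Signals were background-corrected, normalized and put on the log2 scale with neqc of limma 3.58.1 (normexp with negative control parameters inferred from the detection p-values, an offset of 16, and quantile normalization). Of all probes, 23211 had a detection p under 0.05 on at least 3 of the 12 arrays, and 1532 of those had no symbol and were not tested. Each gene was represented by its probe with the highest mean value among those that passed, which left 16301 genes, 4124 of them with more than 1 passing probe. In the tests of single probes, 1 such gene had probes that changed in opposite directions with R5020 in unsynchronized cells, 4 with synchronization in vehicle and 8 with synchronization in R5020, and none of these was a gene named in the text. Symbols were updated through the Entrez identifiers of the probe file and a RefSeq gene table of assembly GRCh38.p14, which was used for names only. This matched 35671 probes and named 14354 of the genes tested; the others keep the name in the probe file. Probe positions are printed as the probe file gives them.

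One linear model with a mean per group was fitted to all 12 arrays with lmFit and eBayes of limma, so the 4 groups shared an estimate of the spread. The comparisons were R5020 against vehicle in unsynchronized cells and in synchronized cells, the difference between these R5020 effects (the interaction), and synchronized against unsynchronized cells in vehicle and in R5020. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05. The main settings, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. By that rule, the text names for each comparison the 8 genes with the highest and the 8 with the lowest log2 difference among those that passed the threshold and whose 3 values in one group all lay on one side of the 3 in the other, passing over symbols that start with LOC. For the interaction the ordering used its own log2 difference, with no condition on overlap. The rule adds up to 4 members of each gene list with the smallest adjusted p, and PGR, ESR1 and CCND1 in every comparison.

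Where a probe was not detected on any of the 3 arrays of a group, its difference between 2 groups is given as a bound, written "at least". Interactions, which combine 4 groups, are given as fitted, and their size is not exact where a group was undetected. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of 2 values, the lowest value among that array's detected probes and the probe's own value.

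The 19 gene lists, chosen from general knowledge of progestin response, the cell cycle and microtubule disruption, covered progestin and glucocorticoid receptor targets, G1/S and DNA replication genes, G2/M genes, histone genes, cyclin, CDK and CDK inhibitor genes, p53 target genes, tubulin genes, SRF and YAP target genes, immediate early and MAPK feedback genes, NF-kB target genes, interferon-stimulated genes, estrogen receptor target genes, secreted growth factor and ligand genes, sterol and fatty acid synthesis genes, unfolded protein response genes, luminal epithelial genes, basal epithelial and mesenchymal genes, metallothionein genes, and stromal, endothelial and immune cell markers. Each list had at least 5 tested members. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists within each comparison (95 tests in all), and again with an estimated correlation and with fry. Members were counted with p-values adjusted over all genes and, separately, adjusted over the list alone.

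Each result was recomputed with no background correction, normexp without negative controls, an offset of 50, cyclic loess or median scaling in place of quantile normalization, the authors' processed values, no detection filter, a filter of detection p under 0.01 on all 12 arrays, every passing probe tested, only the groups compared, moderation with trend and robust options, array weights, the replicate number as a block, and each array left out in turn. A block for the chip was not fitted because the files used do not name the chip.

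The model code was tested on simulated data for the comparison of R5020 with vehicle in unsynchronized cells, with 16623 genes. It recovered 61.2% of genes changed by 1.5-fold, 89.6% of those changed by 2-fold and 93.9% of those changed by 4-fold. Of 176 genes called, 13 were unchanged (7.39%), a share above the threshold of 0.05. The changed genes were drawn from probes above the floor of the signal. Noise was independent between genes, with a spread set slightly below the observed one. The recovered shares therefore do not cover genes near background. Work was done in R 4.3.3 with data.table version 1.17.8, and the plots were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.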

Results

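Expression was profiled in T47D-YB breast cancer cells with stable progesterone receptor B, on 3 arrays each for unsynchronized cells in vehicle, unsynchronized cells in R5020, nocodazole-synchronized cells in vehicle and nocodazole-synchronized cells in R5020. The series title concerns complexes of the progesterone receptor with cyclin D1 and transcription that depends on the cell cycle. The design therefore asks which genes the progestin R5020 changed within 6 hours in each state, whether its effect differed between the states, and what synchronization changed by itself. Between 19797 and 21278 of 47322 probes were detected per array. Across the 16301 genes tested, arrays of the same group correlated at 0.9895 to 0.9927 (12 pairs) and arrays of different groups at 0.972 to 0.9849 (54 pairs). The first principal component held 32.9% of the variance and separated R5020 from vehicle arrays, and the second held 27.1% and separated synchronized from unsynchronized arrays. All differences below are log2 differences ± SE over 3 arrays per group, with limma's adjusted p.

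In unsynchronized cells, R5020 raised SGK1, which encodes a kinase induced by steroid hormones, by 4.49 ± 0.108 (adjusted p = 5.03e-11). PDK4, whose product restrains pyruvate oxidation, rose by 3.86 ± 0.163 (adjusted p = 1.02e-08), and FKBP5, which encodes a co-chaperone of steroid receptors, rose by 3.13 ± 0.108 (adjusted p = 2.28e-09). Several genes were not detected on any vehicle array, so their rises are bounds: at least 32.5-fold for PHACTR3, a regulator of protein phosphatase and actin (adjusted p = 2.25e-11), at least 26.2-fold for the adhesion receptor gene ADGRA2 (adjusted p = 5.03e-11) and at least 12.4-fold for the urotensin precursor gene UTS2B (adjusted p = 3.75e-09). ARMC12 rose by 5.66 ± 0.207 with detection on 1 of 3 vehicle arrays, F3, which encodes tissue factor, by 3.84 ± 0.121, and the potassium channel gene KCNG1 by 3.83 ± 0.0909. The chemokine gene CCL2 fell at least 5.5-fold, to below detection on all 3 R5020 arrays (adjusted p = 5.15e-08). Falls were also measured for SNPH, which tethers mitochondria to microtubules (-2.86), RIPOR3 (-2.71), the guanine nucleotide exchange factor gene VAV3 (-2.67), the stem cell transcription factor gene SOX2 (-2.63), the kinase genes PLK2 (-2.53) and TESK2 (-2.35), and BAMBI, whose product antagonizes TGF-beta signalling (-2.47 ± 0.094, adjusted p = 5.02e-09). CCND1, which encodes cyclin D1, rose by 1.61 ± 0.0919 (adjusted p = 1.41e-07). ESR1, the estrogen receptor gene, fell by 0.74 ± 0.131 (adjusted p = 0.0021), and PGR, the progesterone receptor gene itself, was measured at 0.00 ± 0.0875 (adjusted p = 0.995). Whether the PGR probe also reads the transcript of the integrated vector was not tested, here or in the other comparisons. The probe of SGK1 lay on chromosome 6 from 134532365 to 134532414, that of PHACTR3 on chromosome 20 from 57855873 to 57855922, that of CCL2 on chromosome 17 from 29607909 to 29607958 and that of CCND1 on chromosome 11 from 69178329 to 69178378, in the coordinates of the probe file, which names no genome build.

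In total, R5020 changed 2232 of 16301 genes in unsynchronized cells (13.7%), 1207 upward and 1025 downward, and 4307 had an unadjusted p under 0.05. Of the genes called, 366 rose and 141 fell by at least 2-fold. The share of rises was 54.1%, 70.7% with median scaling in place of quantile normalization, and 48.1% with detection required on all arrays, so the majority direction depends on these choices.

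The progestin and glucocorticoid receptor targets moved most clearly as a list: 16 of 24 rose, 1 fell and 7 did not pass (18 rose and 1 fell when adjusted over the list alone; camera adjusted p = 5.54e-21). Beside SGK1, PDK4 and FKBP5, they included the transcription factor genes KLF15, which rose at least 10.7-fold, and KLF4 (3.17), the cortisol-inactivating enzyme gene HSD11B2 (3.43) and STAT5A (2.90). Of 29 G1/S and DNA replication genes, 7 rose and none fell (9 over the list alone; adjusted p = 7.4e-06), among them CCNE2, which encodes cyclin E2 (1.12 ± 0.123, adjusted p = 4.3e-05), MCM10 (0.95), SLBP (0.74) and GINS2 (0.70). Luminal epithelial genes fell in 11 of 16 cases and rose in none (11 fell over the list alone; adjusted p = 1.65e-07). These included the lineage transcription factor genes FOXA1 (-1.03 ± 0.0988, adjusted p = 1.38e-05), SPDEF (-1.02) and ELF3 (-0.99). Among 30 interferon-stimulated genes, 9 fell and 1 rose (16 fell and 1 rose over the list alone; adjusted p = 0.00197, and adjusted p = 0.2 with an estimated correlation). IFI44 (-0.90), OAS2 (-0.81) and IRF9 (-0.65) fell, and HERC5 rose (1.42). The other calls held with an estimated correlation.

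The remaining lists were not called as lists, though single members changed. Of 21 cyclin, CDK and CDK inhibitor genes 4 rose, namely CCND1, CDC25A (0.89), CCND3 (0.66) and RBL1 (0.66). Among 19 immediate early and MAPK feedback genes, 4 rose and 4 fell, with IER3 (1.80) and MYC (1.43) up and the feedback phosphatase gene DUSP6 (-1.07) and PHLDA1 (-0.88) down. Of 21 NF-kB targets, 5 rose and 3 fell, and the inhibitor gene NFKBIA (1.56) moved against the chemokine genes CCL2 and CCL20 (-2.11). Estrogen receptor targets split at 3 up and 3 down of 20, with GREB1 at least 4.29-fold higher and CA12 up by 1.09, while XBP1 fell (-0.44). Of 23 p53 targets, 4 rose and 2 fell, including the death receptor genes FAS, at least 2.75-fold higher, and TNFRSF10B (1.09). Of 14 growth factor and ligand genes, 3 rose and 2 fell, with the EGF receptor ligand genes TGFA (1.52), EGF (1.48) and HBEGF (0.80) up and PDGFB down (-0.74). Of 9 basal epithelial and mesenchymal genes, 3 rose and 1 fell: EGFR (1.62), CD44 (1.39), ITGA6 (at least 1.56-fold) and TP63 (-1.47). SRF and YAP targets gave 2 rises and 1 fall of 18 (VCL 0.73, ACTA2 0.68, FHL2 -1.55), histone genes 1 rise and 2 falls of 12 (H4C8 0.66), sterol and fatty acid synthesis genes 2 rises of 25, unfolded protein response genes 1 rise and 1 fall of 20 (DNAJB9 0.84, HERPUD1 -1.07). Single falls were found among 30 G2/M genes (CCNF -0.44), 13 tubulin genes (TUBB3 -0.71) and 6 stromal, endothelial and immune cell markers (VWF, at least 1.38-fold lower), and none of 5 metallothionein genes passed at an adjusted or an unadjusted p of 0.05 in limma. Median, mean and test differed in sign for the cyclin, the immediate early and the estrogen receptor lists.

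In synchronized cells, R5020 again raised SGK1 (4.05 ± 0.108, adjusted p = 2.73e-10) and PDK4 (3.71 ± 0.163, adjusted p = 3.04e-08), and PHACTR3 rose at least 16.6-fold (adjusted p = 2.73e-10). The acyl-CoA thioesterase gene ACOT6 rose by 3.94 ± 0.146, ADGRA2 by 3.47, ARMC12 by 3.42 and KCNG1 by 3.37, and the alpha-tubulin gene TUBA3E rose at least 7.42-fold (adjusted p = 3.97e-09). CCL2 fell by 1.83 ± 0.148 (adjusted p = 5.59e-06) and the related chemokine gene CCL20 by 1.65 ± 0.131 (adjusted p = 5.01e-06). TNFRSF11B, which encodes the RANKL decoy receptor osteoprotegerin, fell at least 2.38-fold and the ubiquitin ligase gene NEURL3 at least 2.35-fold. SNPH (-1.56), SOX2 (-1.53), PLK2 (-1.51) and VAV3 (-1.49) fell in this state too. CCND1 rose by 1.16 ± 0.0919 (adjusted p = 4.86e-06), ESR1 fell by 0.82 ± 0.131 (adjusted p = 0.00196), and PGR fell by 0.32 ± 0.0875 (adjusted p = 0.0487).

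R5020 changed 1072 genes in synchronized cells, 633 upward and 439 downward, and 3107 had an unadjusted p under 0.05. With only the groups compared in the fit, 654 were called. The share of rises was 59%, and 74.1% with median scaling. Progestin and glucocorticoid receptor targets rose in 14 of 24 cases and 1 fell (17 and 1 over the list alone; adjusted p = 1.03e-23), including FKBP5 (2.39) and RGS2, a regulator of G-protein signalling, which rose at least 6.49-fold. Luminal epithelial genes fell in 8 of 16 cases (9 over the list alone; adjusted p = 2.22e-09), among them FOXA1 (-1.23) and TFAP2B (-0.97). Both of these calls held with an estimated correlation. Of 30 interferon-stimulated genes 7 fell and none rose (9 fell over the list alone; adjusted p = 2.63e-05, and adjusted p = 0.0645 with an estimated correlation), among them OASL (-1.14), IFIT3 (-1.12), IFIT2 (-0.93) and ISG15 (-0.68). NF-kB targets had 3 rises and 5 falls of 21 (3 and 11 over the list alone; adjusted p = 0.0145, and adjusted p = 0.0645 with an estimated correlation), with TNF (-1.12) falling beside CCL2 and CCL20. Of 29 G1/S and DNA replication genes, 3 rose (3 over the list alone; adjusted p = 0.0034, and adjusted p = 0.0725 with an estimated correlation): CCNE2 (0.83), MCM10 (0.48) and GINS2 (0.46). Of the 13 genes of the tubulin list, which does not hold TUBA3E, 1 rose, TUBE1 (0.82), with the list as a whole shifted upward (1 over the list alone; adjusted p = 0.0241, and adjusted p = 0.0725 with an estimated correlation). Among lists not called, growth factor and ligand genes had 5 rises and 2 falls of 14, with EGF (1.00), TGFA (0.97), HBEGF (0.83) and PDGFA (1.42) up and PDGFB (-0.60) down. Estrogen receptor targets had 2 rises and 2 falls of 20, including GREB1 (1.67) and XBP1 (-0.77). Basal epithelial and mesenchymal genes had 3 rises and 1 fall of 9: EGFR (1.04), CD44 (1.02), KRT6A (at least 1.51-fold) and TP63 (-1.39). Median, mean and test differed in sign for the p53, SRF and YAP, immediate early, estrogen receptor and unfolded protein response lists.

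The R5020 effects in the 2 states, which share no array, had a Pearson correlation of 0.683 and a Spearman correlation of 0.491 across the 16301 genes, which are not independent replicates. Of the genes called, 503 rose in both states against 46.9 that independent lists would share, 287 fell in both against 27.6, and 3 moved in opposite directions. The lists were called with a shared estimate of each gene's spread, which can raise the overlap by itself. The numbers for independent lists are therefore not a strict reference. SGK1, PHACTR3, PDK4 and KCNG1 were among the shared rises, and CCL2, SNPH, SOX2 and VAV3 among the shared falls. The plot of R5020 effects in both states shows this shared response together with the genes whose effect differed.

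**Figure D1:**
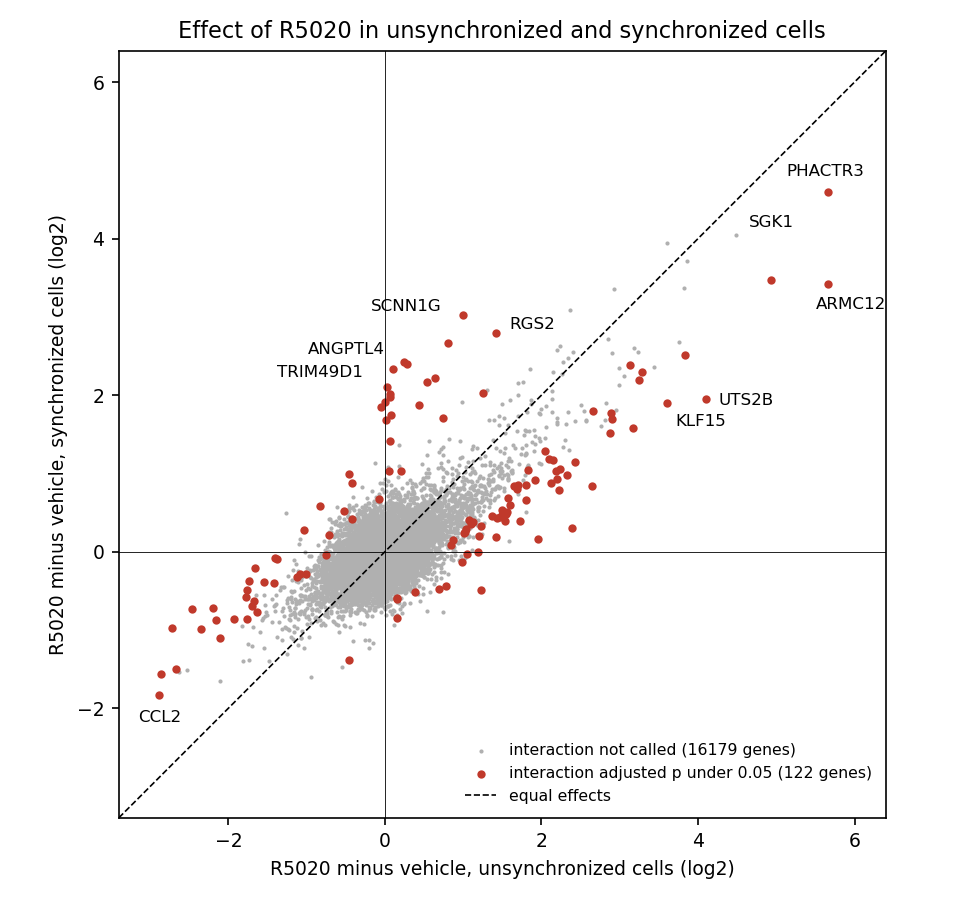
Log2 difference of R5020 against vehicle for 16301 genes in unsynchronized cells (x axis) and synchronized cells (y axis), with the 122 genes called in the interaction test in red and a dashed line where both effects are equal. PHACTR3 and SGK1 lie far up in both states, ARMC12, UTS2B and KLF15 lie below the line, and ANGPTL4 and several TRIM genes lie near 0 on the x axis and above 1.5 on the y axis.

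The effect of R5020 differed between the states for ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase: it was 0.24 ± 0.123 in unsynchronized cells (adjusted p = 0.239) and 2.42 ± 0.123 in synchronized cells, an interaction of 2.18 ± 0.174 (adjusted p = 0.000179). A group of TRIM genes on chromosome 11 followed the same pattern, with interactions of 2.23 ± 0.249 for TRIM49D1 (adjusted p = 0.00115), 2.11 for TRIM53CP, 2.08 for TRIM48 and 1.89 for TRIM53AP. In synchronized cells R5020 raised TRIM49D1 at least 4.04-fold and TRIM48 at least 3.63-fold, and in unsynchronized cells neither was detected on any array. The sodium channel subunit gene SCNN1G (2.02), the caveola gene CAVIN2 (1.95) and the pseudogene GRM5P1 (1.92) also had larger R5020 effects in synchronized cells. Smaller effects in synchronized cells were measured for ARMC12 (-2.24 ± 0.293, adjusted p = 0.00254), UTS2B (-2.14), GP2 (-2.09), the prostaglandin E synthase gene PTGES (-1.81), the stress-response gene NUPR1 (-1.79), ANOS1 (-1.71), KLF15 (-1.70 ± 0.164, adjusted p = 0.001) and KLF4 (-1.60). KLF15 rose at least 10.7-fold in unsynchronized and at least 3.01-fold in synchronized cells, and ANOS1 rose at least 1.86-fold in unsynchronized cells while its difference in synchronized cells did not pass (adjusted p = 0.0914). No array of at least 1 group detected TRIM49D1, TRIM48, TRIM53CP, TRIM53AP, CAVIN2, GRM5P1, SCNN1G, UTS2B, KLF15 or ANOS1, so the sizes of their interactions depend on the floor of the signal. ARMC12 was detected on 1 of 3 vehicle arrays in each state, and GP2 on 1 of 3 unsynchronized vehicle arrays. The sizes of these interactions depend on the floor too. The interaction did not pass for CCND1 (-0.45 ± 0.13, adjusted p = 0.195), PGR (-0.32, adjusted p = 0.365) or ESR1 (-0.08, adjusted p = 0.938). The TRIM48 probe lay on chromosome 11 from 54794809 to 54794858, that of TRIM49D1 on chromosome 11 from 89293168 to 89293217 and that of ANGPTL4 on chromosome 19 from 8345182 to 8345231, in the coordinates of the probe file.

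The interaction was called for 122 genes, 55 positive and 67 negative, and 1709 had an unadjusted p under 0.05. The count was 217 without background correction (84 positive and 133 negative), 194 with a neqc offset of 50 and 213 with the authors' processed values, and fell to as few as 60 (35 positive and 25 negative) with 1 array left out. The R5020 effect was smaller in synchronized cells in size for 93 of them and larger for 29, and 20 of the 122, such as ANOS1 and TUBB3, had fitted effects of opposite sign in the 2 states, whether or not each passed. Of the 122, R5020 changed 65 in both states, 37 in unsynchronized cells alone and 20 in synchronized cells alone. Progestin and glucocorticoid receptor targets had 6 negative interactions and 1 positive of 24 (9 and 1 over the list alone; adjusted p = 7.5e-05), a call that held with an estimated correlation. STAT5A (-1.20) and F3 (-1.32) joined KLF15 and KLF4 on the negative side, and RGS2 (1.37) was positive. The G1/S and DNA replication list shifted downward (adjusted p = 0.0284, and adjusted p = 0.248 with an estimated correlation), although none of its 29 members passed singly in limma, adjusted over all genes or over the list alone, and 4 had an unadjusted p under 0.05. Of the remaining lists, none called, single members passed: NFKBIA (-1.05) and CCL2 (1.05) among NF-kB targets, IER3 (-1.14) and MYC (-1.001) among immediate early genes, HERC5 (-1.23), GDF15 (-1.01), KRT6A (0.97) and TUBB3 (0.93), of which CCL2, GDF15 and KRT6A, like RGS2, were undetected in at least 1 group. The CCL2 interaction was -0.07 without background correction (adjusted p = 0.92), so it rests on how signals near background are treated. Median, mean and test differed in sign for the histone, immediate early, interferon, growth factor and sterol lists.

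**Figure D2:**
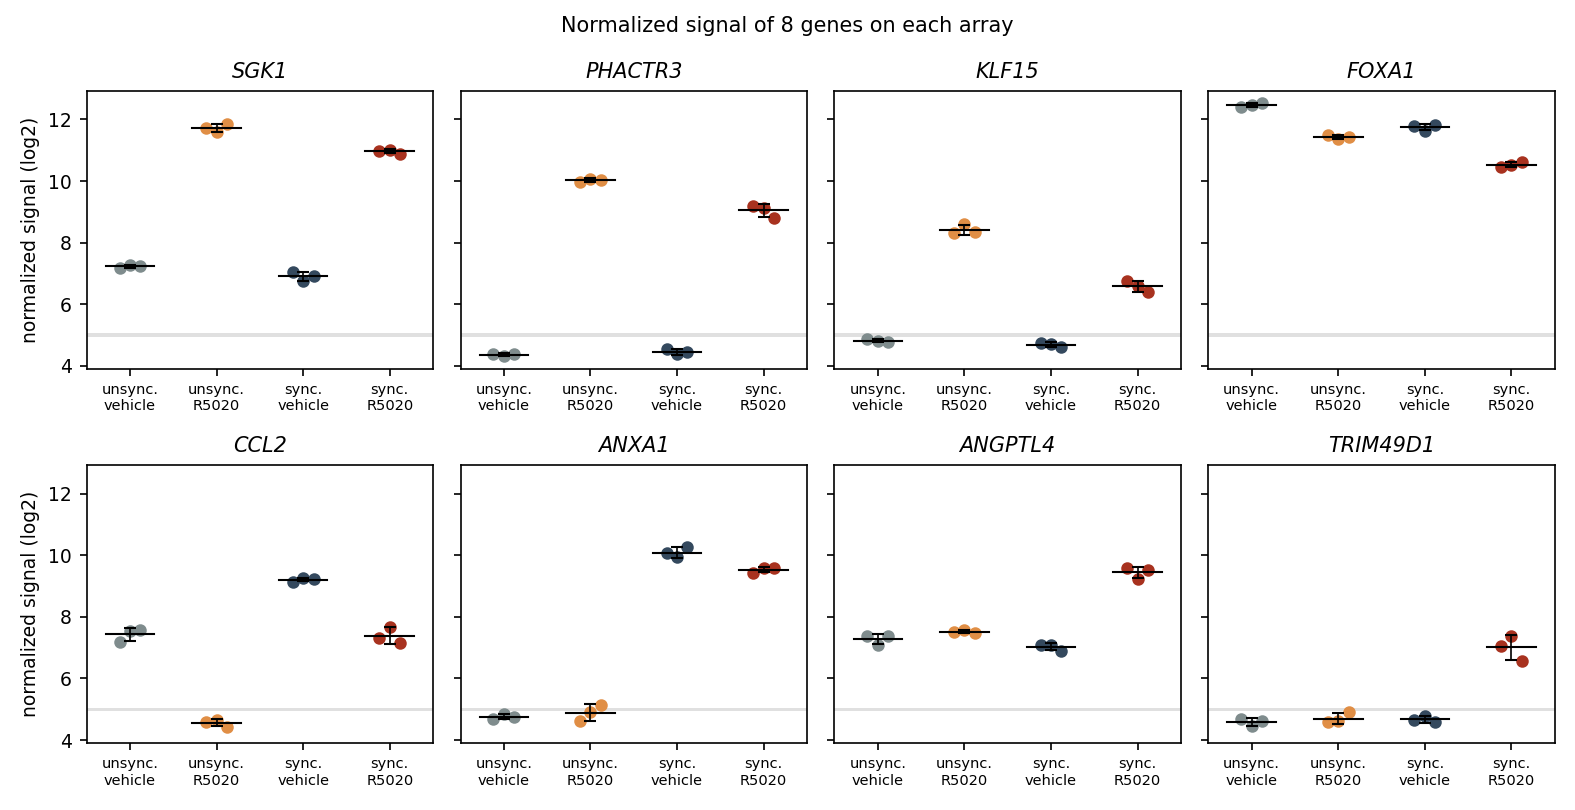
Normalized log2 intensity of SGK1, PHACTR3, KLF15, FOXA1, CCL2, ANXA1, ANGPTL4 and TRIM49D1 in the 4 groups, with points for single arrays, lines for means, bars for the SD of 3 arrays and a grey band from 4.939 to 5.051 for the lowest value among detected probes. TRIM49D1 rose above the band only in synchronized cells with R5020, ANXA1 rose with synchronization under both treatments, and CCL2 lay below the band in unsynchronized cells with R5020.

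Synchronization by itself, compared in vehicle, raised ANXA1 from below detection by at least 34-fold (adjusted p = 5.38e-10); its product, annexin A1, is a membrane-binding mediator of glucocorticoid action. The cornified envelope genes SPRR3 and SPRR1A rose by 2.74 ± 0.121 (adjusted p = 1.13e-07) and 2.31 ± 0.137, the keratin gene KRT80 by 2.19 ± 0.127, and the small heat shock protein gene HSPB8 by 2.15 ± 0.157. KLF4 (2.71), the cytokine gene TNF (2.38, detected on 1 of 3 unsynchronized arrays) and the interferon-induced gene IFIT2 (2.38) rose as well. SRARP, a gene tied to steroid receptors in breast cells, fell by 2.63 ± 0.213 (adjusted p = 1.49e-05). The beta-tubulin gene TUBB fell by 1.42 ± 0.109 (adjusted p = 1.19e-05), as did the tubulin pseudogenes TUBBP1 (-1.54) and TUBAP2 (-1.36), whose probes can bind transcripts of related genes. The other falls were MIR1228 (-1.79), ACOT6 (-1.53), CLDND2 (-1.51) and the keratin pseudogene KRT8P44, at least 2.58-fold. ESR1 fell by 0.90 ± 0.131 (adjusted p = 0.0011), while CCND1 (0.02, adjusted p = 0.916) and PGR (0.09, adjusted p = 0.581) did not pass.

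Of 30 G2/M genes, 17 rose and 4 fell (19 and 5 over the list alone; camera adjusted p = 4.94e-06). The mitotic kinase gene PLK1 rose by 1.21 ± 0.242, CKS2 by 1.06, the cyclin B1 gene CCNB1 by 0.88 and the kinesin gene KIF20A by 0.75, whereas TOP2A (-1.08), the ubiquitin-conjugating enzyme gene UBE2C (-0.94), CDK1 (-0.87) and CENPF (-0.77) fell. Histone genes rose in 8 of 12 cases and fell in 1 (11 and 1 over the list alone; adjusted p = 1.9e-07), with H4C8 (1.52) and H1-2 (1.05) up and H4C3 (-1.29) down. NF-kB targets rose in 12 of 21 cases and none fell (15 over the list alone; adjusted p = 2.86e-10), led by TNF, CCL20 (1.83), CCL2 (1.77) and CXCL1 (1.37). Interferon-stimulated genes rose in 17 of 30 cases and 1 fell (18 and 1 over the list alone; adjusted p = 2.86e-10), with IFIT1 at 2.05 and ISG20 at 1.91. Of 19 immediate early and MAPK feedback genes, 9 rose and 1 fell (10 and 1 over the list alone; adjusted p = 0.000185), with ATF3 (1.77), MYC (1.62) and JUN (1.55) up and SPRY1 (-0.79) down. SRF and YAP targets rose in 7 of 18 cases (8 over the list alone; adjusted p = 8.28e-06), including ANKRD1, at least 3.07-fold, CCN1 (0.97), TPM1 (0.95) and ACTA2 (0.81). Of 23 p53 targets, 3 rose and none fell (3 over the list alone; adjusted p = 0.0129), namely CDKN1A (0.56), TNFRSF10B (0.70) and AEN (0.53). Luminal epithelial genes fell in 8 of 16 cases and 1 rose (8 and 1 over the list alone; adjusted p = 0.000237), with GATA3 (-0.73), FOXA1 (-0.71) and SPDEF (-0.62) down. Metallothionein genes rose in 3 of 5 cases (3 over the list alone; adjusted p = 0.00393, and adjusted p = 0.0813 with an estimated correlation), with MT2A at 0.75. Sterol and fatty acid synthesis genes fell in 6 of 25 cases (6 over the list alone; adjusted p = 0.0268, and adjusted p = 0.184 with an estimated correlation), FASN by 0.94 and INSIG1 by 0.54. G1/S and DNA replication genes fell in 3 of 29 cases (3 over the list alone; adjusted p = 0.0159, and adjusted p = 0.104 with an estimated correlation): UNG (-0.83), CCNE2 (-0.69) and MCM6 (-0.48). The other calls held with an estimated correlation.

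Lists not called in vehicle included the tubulin genes, which parted in direction: 3 of 13 rose and 5 fell (adjusted p = 0.294), with TUBB2B up (1.17) and TUBB4B (-0.84) and TUBA1C (-0.64) down beside TUBB. Of 24 progestin and glucocorticoid receptor targets, 5 rose and 2 fell, among them KLF4 and DUSP1 (1.39). Estrogen receptor targets gave 3 rises and 2 falls of 20, with the retinoic acid receptor gene RARA up (1.03). Of 21 cyclin, CDK and CDK inhibitor genes, 2 rose and 1 fell, CDC25B (0.75) and CDKN1A against CDKN1C (-1.02). Unfolded protein response genes rose in 2 of 20 cases, led by DDIT3 (1.61), growth factor and ligand genes in 3 of 14, with GDF15 at least 1.59-fold higher, and basal epithelial and mesenchymal genes rose in 2 and fell in 1 of 9 (CD44 1.02, TWIST1 -0.55). Of 6 stromal, endothelial and immune cell markers, VWF fell (-0.48). Median, mean and test differed in sign for the progestin and estrogen receptor lists. In all, synchronization in vehicle changed 1922 genes, 963 upward and 959 downward, with 4227 at an unadjusted p under 0.05, and 1242 were called with 1 unsynchronized vehicle array left out. The share of rises was 50.1%, and 31.3% with median scaling.

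Under R5020, synchronization raised ANXA1 by 4.64 ± 0.139 (adjusted p = 2.9e-09; detected on 1 of 3 unsynchronized arrays), HSPB8 by 3.44 ± 0.157 (adjusted p = 9.98e-08) and the tight junction gene CLDN1 by 3.42 ± 0.125 (adjusted p = 1.67e-08). TRIM51 rose by 3.41 ± 0.137, TRIM53CP by 3.01, the guanylate-binding protein gene GBP1 by 2.52 and KRT80 by 2.52, and CCL2 rose at least 5.29-fold (adjusted p = 3.12e-07). The falls were those of ARMC12 (-2.32 ± 0.207, adjusted p = 1.88e-05), UTS2B (-2.14), KLF15 (-1.83), PNKD (-1.74), GP2 (-1.68), C6orf141 (-1.67), the mitochondrial carrier gene SLC25A18 (-1.58) and the phospholipase gene PLA2G10 (-1.56). CCND1 fell by 0.43 ± 0.0919 (adjusted p = 0.0081), ESR1 by 0.98 ± 0.131 (adjusted p = 0.000424), and PGR did not pass (-0.23, adjusted p = 0.103). Synchronization in R5020 changed 2201 genes, 1075 upward and 1126 downward, with 4366 at an unadjusted p under 0.05. The share of rises was 48.8%, and 27.7% with median scaling.

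In this treatment 17 of 30 G2/M genes rose and 5 fell (18 and 5 over the list alone; adjusted p = 2.84e-06), with CCNB1 (1.11), PLK1 (1.07) and KIF20A (1.02) up and CDK1 (-1.21) and UBE2C (-0.95) down. Histone genes rose in 9 of 12 cases and 1 fell (11 and 1 over the list alone; adjusted p = 9.52e-07), H4C8 by 1.62 against H4C3 at -1.49. Interferon-stimulated genes rose in 15 of 30 cases and 1 fell (17 and 3 over the list alone; adjusted p = 9.12e-08), with ISG20 (2.13), IFIT1 (2.09) and IFI44 (1.61) up and HERC5 (-0.64) down. Of 21 NF-kB targets, 7 rose and 1 fell (7 and 2 over the list alone; adjusted p = 0.000787), with CCL20 at 2.30 and TNF at least 2.23-fold higher, against NFKBIA at -0.65. SRF and YAP targets rose in 10 of 18 cases and 1 fell (11 and 1 over the list alone; adjusted p = 1.88e-06), including FHL2 (1.55) and CCN1 (1.12). Immediate early and MAPK feedback genes rose in 8 of 19 cases and 2 fell (8 and 2 over the list alone; adjusted p = 0.00146), JUN by 2.05 and ATF3 by 1.70. G1/S and DNA replication genes fell in 10 of 29 cases (12 over the list alone; adjusted p = 4.2e-06), among them CCNE2 (-0.97), UNG (-0.67) and SLBP (-0.65). Progestin and glucocorticoid receptor targets parted, with 10 of 24 lower and 5 higher (10 and 5 over the list alone; adjusted p = 0.0174), KLF15 and ATP1B1 (-1.24) against DUSP1 (1.76) and RGS2 (1.56). Luminal epithelial genes fell in 5 of 16 cases and 1 rose (7 and 1 over the list alone; adjusted p = 0.0118, and adjusted p = 0.0739 with an estimated correlation). Metallothionein genes rose in 3 of 5 cases (3 over the list alone; adjusted p = 0.00222, and adjusted p = 0.0665 with an estimated correlation), MT2A by 1.24, and sterol and fatty acid synthesis genes fell in 5 of 25 cases (7 fell and 1 rose over the list alone; adjusted p = 0.0281, and adjusted p = 0.205 with an estimated correlation), FASN by 1.02. The other calls held with an estimated correlation. Median, mean and test differed in sign for the cyclin and the basal epithelial lists, neither of them called.

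The synchronization effects in vehicle and in R5020, which share no array, correlated at 0.615 (Pearson) and 0.513 (Spearman) across genes. Of the genes called, 540 rose in both treatments against 63.5 for independent lists, 479 fell in both against 66.2, and 20 moved in opposite directions. Here too the lists shared an estimate of each gene's spread, so the numbers for independent lists are not a strict reference. ANXA1, HSPB8, KRT80 and CCL2 rose, and TUBB and ESR1 fell, under both treatments. The directions of the lists called in each comparison did not flip with cyclic loess or median scaling, and the plot of list medians sets them side by side.

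**Figure D3:**
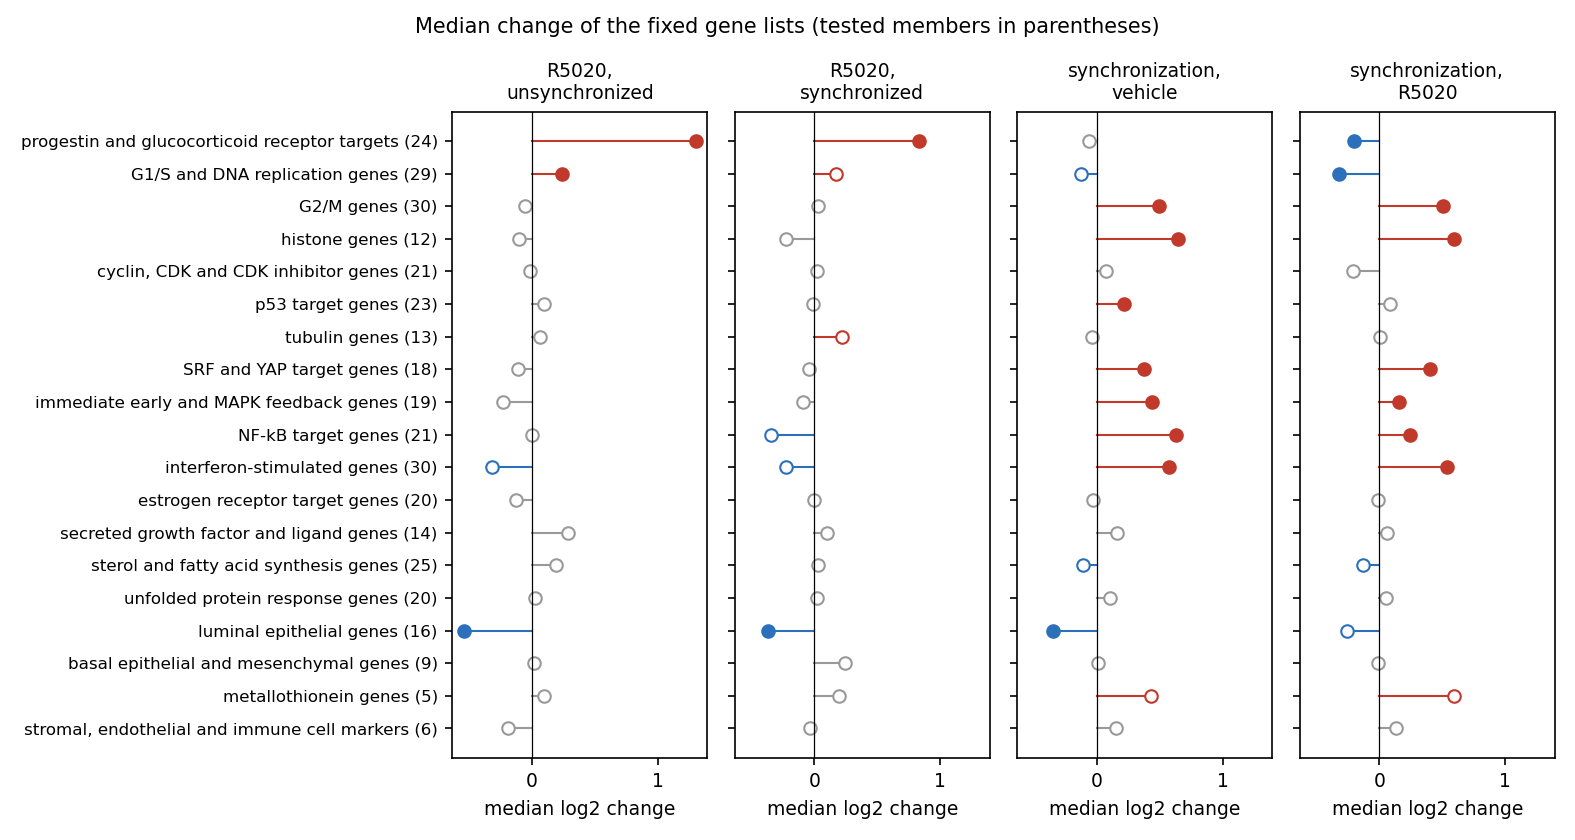
Median log2 difference of the tested members of each of the 19 gene lists (x axis) in the comparisons of R5020 with vehicle and of synchronized with unsynchronized cells, with a coloured outline where camera called the list, a filled marker where the call held with an estimated correlation, and grey where it was not called. Progestin and glucocorticoid receptor targets lie to the right with R5020 in both states, luminal epithelial genes lie to the left throughout, and NF-kB, interferon and histone lists lie to the right with synchronization.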

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

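The results below were singled out because the test of a difference between the 2 synchronization states passed for the R5020 effect. The test of a single lower share of responding cells and the regroupings with the average R5020 effect removed were chosen only after the result was seen.

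The R5020 effect differed between synchronized and unsynchronized cells for 122 genes, and for the progestin and glucocorticoid receptor targets (camera adjusted p = 7.5e-05) and the G1/S and DNA replication genes (adjusted p = 0.0284, and adjusted p = 0.248 with an estimated correlation) as lists. Negative differences included those of ARMC12 (-2.24), UTS2B (-2.14), GP2 (-2.09), PTGES (-1.81), NUPR1 (-1.79), ANOS1 (-1.71), KLF15 (-1.70) and KLF4 (-1.60). Positive ones included those of TRIM49D1 (2.23), ANGPTL4 (2.18), TRIM53CP (2.11), TRIM48 (2.08), SCNN1G (2.02), CAVIN2 (1.95), GRM5P1 (1.92) and TRIM53AP (1.89). Members of the gene lists that differed included F3 (-1.32), HERC5 (-1.23), STAT5A (-1.20), IER3 (-1.14), NFKBIA (-1.05), GDF15 (-1.01) and MYC (-1.001). Members with a positive difference included TUBB3 (0.93), KRT6A (0.97), CCL2 (1.05) and RGS2 (1.37). Where a group was undetected, as for TRIM49D1, TRIM48, CAVIN2, GRM5P1, TRIM53AP, TRIM53CP, SCNN1G, KRT6A, UTS2B, KLF15, ANOS1, GDF15, CCL2 and RGS2, the size depends on the floor of the signal, and no order among the genes follows from it. ARMC12, GP2 and F3 were detected on only some vehicle arrays, so their sizes depend on that floor too. When R5020 and vehicle were regrouped within each state, 6 of 100 regroupings, the real one included, called as many as 122 genes, with up to 2994 in another. Of the others, 85 mixed the treatments in both states and called at most 1 gene, while 13 kept the R5020 split in 1 state and called up to 818, and 1 turned it in 1 state and called 2994. With the average R5020 effect removed, none of them reached 122 (highest 1, limma). The removal cancels the interaction by construction where R5020 was turned in 1 state. Where the split was kept in 1 state, it leaves only part of the interaction. For those regroupings the counts after removal decide nothing about chance. The count of 6 met the bound set beforehand for chance as the explanation. However, the other regroupings that reached 122 carry the R5020 effect of 1 state by construction, so the count of 6 decides nothing about chance.

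R5020 effects were smaller in synchronized cells across the response. Among 328 genes with an average R5020 effect of at least 1 log2 unit, 265 (80.8%) had a smaller effect in synchronized cells. The median ratio was 0.705 and the median size difference was -0.482. Singly, 57 of the 328 passed the interaction test with a smaller effect and 14 with a larger one. The 95% interval of the share, 76.1 to 84.9, treats genes as independent, which they are not. It does not measure the spread between arrays. Between-array normalization and background correction are argued against as the cause, since the median size difference stayed at -0.297 or below over the alternatives, and so is nearness to background, since 188 of 216 genes detected on all arrays (87%) had a smaller effect. A single lower share of responding cells stays open: 14 genes passed with a larger effect in synchronized cells, a count that met both the bound set for this cause and the bound set against it, and only ANGPTL4, FAM43A and RCAN1 of them were detected on all arrays. The biological explanation the design offers, the synchronization state, stays open too, because nocodazole exposure and cell-cycle position were not separated. A smaller effect was not always a lower final level. In vehicle, synchronization had already raised KLF4 (2.71), NUPR1 (1.33) and PTGES (0.99), and KLF4 was higher in R5020 too (1.12). ARMC12 did not pass in vehicle (-0.08, limma adjusted p = 0.854), and UTS2B and KLF15 were undetected in vehicle in both states. How far raised vehicle levels account for smaller effects was not tested.

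Probes of TRIM48, TRIM49D1, TRIM49D2, TRIM51, TRIM53AP and TRIM53CP, 6 of 34 probes of this family, rose together in synchronized cells with R5020, with interactions of 1.62 to 2.23. The 6 were picked because their interaction passed, and most of the other probes failed the detection filter and were not tested. Other TRIM53AP probes, not tested, had interactions of 0.845 and -0.0272. However, TRIM51 (1.79, limma adjusted p = 1.16e-05) and TRIM53CP (at least 1.31-fold, adjusted p = 0.00354) also rose with synchronization in vehicle. One transcript read by several probes stays open: 0% of 15 pairs of the 6 rising probes shared a stretch of 25 bases (the longest was 9). Aligned without gaps, the pairs were at best 28.6% to 51.1% identical. The lack of shared stretches had been set down beforehand as evidence against this cause. It cannot exclude it, since the probes were not placed on transcripts and probes at different places of 1 transcript would share none. A wider gene programme of the transcription factor DUX4 stays open as well: the median interaction over 47 probes of its other targets was 0.016, below the bound set beforehand against it, but only 9 of them passed the detection filter and were tested (0 called in limma), so that bound was read mostly from probes at the floor. Synchronization state as the biological cause stays open.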

How the results depend on the processing

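Most values kept their direction and their side of the threshold: of 7700 recomputed values of 313 called named results, 7340 stayed the same, 358 fell short of the threshold and 2 reversed, and of 3271 recomputed values of 135 uncalled ones, 3071 stayed and 200 passed. The reversed values were those of the CCL2 interaction, at -0.06866 without background correction and -0.06802 with the authors' processed values. R5020 in synchronized cells changed 654 genes when only the groups compared were fitted, with fewer arrays. The interaction was called for 217 genes without background correction, 194 with a neqc offset of 50, 213 with the authors' processed values and 78 with a replicate block (41 positive and 37 negative, against 55 and 67). The correlation of R5020 effects was 0.742 without background correction, 0.726 with normexp without negative controls, 0.752 with the authors' processed values, 0.624 without a detection filter and 0.74 with detection on all arrays. Of 34 list calls, 22 remained with an estimated correlation, and fry called 53. The cause was not tested. Leaving out single arrays gave 1646 to 2283 genes for R5020 in unsynchronized cells, 776 to 1057 in synchronized cells, 60 to 109 for the interaction, 1242 to 1936 for synchronization in vehicle, 1515 to 2196 in R5020, and a correlation of 0.654 to 0.675. The interaction count fell by more than 1.5 times without any 1 of the 3 arrays of either unsynchronized group, synchronized vehicle arrays 2 or 3, or synchronized R5020 array 3, and the vehicle count without unsynchronized vehicle array 1 or 2. Arrays with the same replicate number correlated weakly once group means were removed (18 correlations from -0.033 to 0.0638, none above 0.1). Since 8 of 12 arrays correlated best with their own number, a weak pairing is not excluded. A slide block was not run, since no chip is named, and an interaction fitted on only the groups compared gives no value. Signal near background limits folds to bounds where a group was undetected.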

Other observations

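The test of more short RNA of every kind and the screen of gene families were chosen only after the result was seen. Probes of part of the small nuclear RNA genes rose with synchronization, together with those of histone genes. Whether the amount of these RNAs and of the ribosomal RNAs below changed, or only their labelling, was not tested. In vehicle, RNU6ATAC rose by 1.42, RNU4-2 by 1.17, RNU1-1 by 0.76, RN7SK by 0.75 and RNU6-1 by 0.70, which encode spliceosomal RNAs and the RNA that restrains elongation factor P-TEFb, and 5 of 10 small nuclear RNA genes rose (6 of 10 in R5020). The median over the 10 genes was 0.55 in vehicle and 0.61 in R5020, while RNU11 (-0.32) and RNU4ATAC (-0.25) did not pass in vehicle. As a family, RNU genes were called in vehicle (camera adjusted p = 0.0367, and adjusted p = 0.858 with an estimated correlation) and in R5020 (adjusted p = 0.0113, and adjusted p = 0.78 with an estimated correlation). More short RNA of every kind in the synchronized preparations met the bound set against it. The median over 115 small nucleolar RNA genes was -0.085 in vehicle (95% interval -0.2 to -0.0086). However, the small nuclear RNA median behind that bound had a 95% interval of 0.0087 to 0.96. What the small nucleolar RNA probes read was not tested. The values therefore argue only against a rise shared by all short RNA probes. Both intervals were drawn over genes, which are not independent replicates. Between-array normalization is argued against for the histone list, whose median stayed at 0.441 or above over the alternatives, against 0.642 as reported. Synchronization state as the biological cause stays open.

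Of 3 ribosomal RNA probes, 2 rose with synchronization. RNA28SN5 rose by 1.28 in vehicle (adjusted p = 9.12e-05) and 0.95 in R5020, and RNA5S9 by 1.63 and 1.52. RNA18SN5 did not pass in vehicle (0.57, adjusted p = 0.0637) or in R5020 (-0.02, adjusted p = 0.97). LOC100132564 rose by 5.42 and 5.37, but which transcript its probe reads is not known. The probe shares no 16-base stretch with the ribosomal probes. Probes at different places of a transcript would share none, so a ribosomal source is not excluded.

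A screen of 494 gene families by symbol stem called 16 family results with camera, of which 0 were called with an estimated correlation (adjusted p from 0.228 to 0.858). R5020 in unsynchronized cells raised NBPF genes (6 of 12, median 0.57, adjusted p = 0.00121) and KLF genes (5 of 12, 0.46, adjusted p = 0.00455) and lowered HOXC genes (5 of 7, -0.48, adjusted p = 0.00835) and CCL chemokine genes (4 of 8, -0.66, adjusted p = 0.00835). In vehicle, synchronization raised NPIPB genes (9 of 12, median 0.54, adjusted p = 3.4e-06), and in R5020 7 of them rose (0.56). NBPF and NPIPB are families of closely similar copies, and cross-reading of their probes was not tested.

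Every split of the 6 arrays of a comparison was also tested, with the other 6 arrays kept in the fit under their own groups. The real split was the only 1 of 10 that called as many genes for R5020 in unsynchronized cells (2232, against at most 1 in another split), R5020 in synchronized cells (1072, at most 0), synchronization in vehicle (1922, at most 1) and synchronization in R5020 (2201, at most 0). With 10 splits no share under 0.05 can be reached.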
